A study of Caenorhabditis elegans with 16 samples.

How the data were processed

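Whole larvae of the nematode Caenorhabditis elegans were profiled by total RNA sequencing in 4 genotypes: wild type (WT), an lsm-8 deletion mutant, a met-2 set-25 deletion double mutant, and a triple mutant that carries all of these deletions. Per the labels, the animals were grown on OP50 bacteria and sorted by size for the L3 to L4 larval stages and, by their pharynx, for the absence of the green fluorescent balancer chromosome. The double mutant and WT carry no balancer and went through the same sorting. RNA was depleted of ribosomal RNA with Ribo-Zero Gold, and libraries were made with the ScriptSeq v2 kit and sequenced as short single-end reads on an Illumina HiSeq instrument. The labels give 4 independent biological replicates per genotype, or 16 libraries. The sample titles number 2 libraries per genotype as the study's replicates and mark the other 8 as unused. Among the unused ones, 3 libraries, all of set 2 and 1 from each mutant genotype, are described as poorly sorted because they held many reads on the deleted sequences. Libraries are named here by genotype and set number (WT 1, lsm-8 4).

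The authors deposited tables of raw counts, per the labels the number of reads per gene, per annotated repeat copy and per splice junction, each with a table of normalized values. The genes, repeats and junctions tables held 20182, 96340 and 230711 features. The authors' normalized values are on a log2 scale: recomputing log2 of the count times the mean library total over the library's own total, plus 8, gave the deposited value of each feature to within 0.001. Bowtie is the only aligner the labels name; its version, the genome build, the annotation and the strand that was counted are not given in the sources used here. No column of values per sample was left unread. Of the 20182 gene identifiers, 18778 had a symbol in the name table and 19513 had coordinates in the WBcel235 annotation. Positions of junctions and repeats are those of the deposited tables, and their build is not given: only 2.73% of the 88118 junctions with at least 20 reads equalled an intron of WBcel235. Junctions were therefore given a gene by matching the lengths of consecutive introns and the exon between them to the annotation, which named a gene for 87.0% of them. A called junction without a match took the gene of its cluster.

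Changes were tested from the raw counts with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, quasi-likelihood fits with glmQLFit, and Benjamini-Hochberg adjustment, with a call at an adjusted p under 0.05. The planned design, fixed before the data were examined, fits the 8 libraries the study used, with no replicate term because the titles do not state a pairing. In that fit 17251 genes were tested. A second planned fit on the 13 libraries not marked as poorly sorted (4 of WT and 3 of each mutant) tested 17126 genes and is reported beside it, as is the planned fit that adds the mean log2 CPM (counts scaled to the library total) of the sperm list as a covariate for age. Comparisons were lsm-8, met-2 set-25 and the triple mutant with WT, the triple mutant with each of the other mutants, and the interaction, which tests whether the change with loss of lsm-8 differs without met-2 and set-25. Repeats were tested per copy and summed by repeat name (called family here), with library sizes and TMM factors of the gene table. Junctions that share an end formed clusters (igraph 2.1.4); those with at least 10 reads in each of 2 libraries were tested with diffSpliceDGE for a change of share within the cluster. Fold changes are on the log2 scale with standard errors (SE) from the fits, and mean CPM are given with standard deviations (SD) over the libraries not marked as poorly sorted. A p-value without another name comes from edgeR.

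Gene lists, 28 in number, were fixed before the data were examined: LSM proteins, RNA decay factors, H3K9 methylation, Polycomb, spliceosome, homeobox genes, germline, sperm, oocyte and yolk, cuticle collagens, molting, hedgehog-related genes, C-type lectins, lysozymes and immune response, intracellular pathogen response (the pals genes), heat shock, detoxification enzymes, nuclear hormone receptors, chemoreceptors, F-box and MATH genes, histones, ribosomal proteins, neuropeptides and insulins, body wall muscle, pharynx, intestine, neurons, and mitochondrially encoded genes. The last had 0 members in the gene table and could not be tested. There were also 6 lists of repeats. Lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01 and with the correlation estimated, adjusted over the lists of a comparison. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. The genes named follow a rule fixed in advance: the 3 deleted genes; the 10 with the largest change each way (5 in the last 2 comparisons) among calls with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries; up to 3 called members of each list with the smallest adjusted p; and for repeats and junctions the 5 each way with the smallest adjusted p. The rule was applied to both fits. Chromosome arms were the outer 2 of 3 equal parts of each autosome, compared with Fisher's exact test.

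Gene totals ran from 48498058 to 64887212 reads per library, repeat totals from 200679 to 336469 and junction totals from 5566089 to 7444740. Alternatives were DESeq2 1.42.0, limma on the authors' normalized values, RLE size factors, no count filter or a filter of 50 counts in 2 libraries, a minimum absolute log2 fold change of 1, the 4 compared libraries alone, all 16 libraries, the study's replicate number or the set number as a block, TMM from the repeat counts, a minimum of 30 reads per junction, the outer 2 of 4 parts as arms, and leaving out each library in turn. Added after seeing the data were DESeq2 and leave-one-out on the 13 libraries, the first principal component as a covariate, fits without pairs of libraries that stood apart, the sperm covariate for repeats and junctions, and a list of LTR elements limited to names of CER followed by a digit. Chromosome arms, genes shared by lsm-8 and the triple mutant, and levels of the deleted genes were planned on the 8 libraries, and their values on 13 were not planned. Tests of rare junctions and of donors and acceptors were not part of the planned design either. The pipeline was tested on simulated data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.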

Results

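RNA was measured in whole L3 to L4 larvae of 4 genotypes with 4 libraries each. The gene tables held 48498058 to 62319484 reads per WT library and 57099795 to 64887212 per met-2 set-25 library. They held 55563862 to 59949486 reads per lsm-8 library and 53917798 to 61272349 per library of the triple mutant. The study used 2 libraries per genotype, and 13 libraries (4 of WT and 3 of each mutant) were not marked as poorly sorted. The series concerns how the nuclear LSM2-8 complex, which binds the 3' ends of RNA and takes part in splicing and decay, keeps genes in repressed chromatin silent. The genotypes here join its loss to that of MET-2 and SET-25, the enzymes that methylate histone H3 lysine 9 in this worm.

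The transcript of lsm-8 (WBGene00003082, chromosome IV from 6326526 to 6329472 in WBcel235) stood at 23.5 CPM ± 5.12 (SD, n = 4) in WT and 18.2 ± 2.14 (n = 3) in met-2 set-25. It stood at 1.73 CPM ± 1.47 (n = 3) in lsm-8 and 2.16 ± 3.11 (n = 3) in the triple mutant. The libraries of these strains were uneven, since lsm-8 1 kept 14.6% of the WT mean and triple 1 kept 24.5%, against 0.904% to 4.09% in the other 4. The log2 fold change was -3.89 ± 0.95 (SE) in lsm-8, where the adjusted p of 0.0732 missed the threshold, and -3.66 ± 0.94 in the triple mutant (adjusted p = 0.0416, 13 libraries). The met-2 transcript (WBGene00019883, chromosome III from 8375300 to 8380848) fell from 261 CPM ± 66.0 in WT to 84.9 ± 7.51 in met-2 set-25 (adjusted p = 0.000804 by edgeR) and 120 ± 8.06 in the triple mutant. The set-25 transcript (WBGene00012802, chromosome III from 13283824 to 13293090) went from 49.4 CPM ± 18.2 in WT to 17.6 ± 4.02 in met-2 set-25 (adjusted p = 0.0232 by edgeR) and 29.03 ± 3.057 in the triple mutant (adjusted p = 0.0501 by edgeR). The same 3 genes kept their direction in the 8 libraries of the study, but 0 passed the threshold in edgeR.

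**Figure D1:**
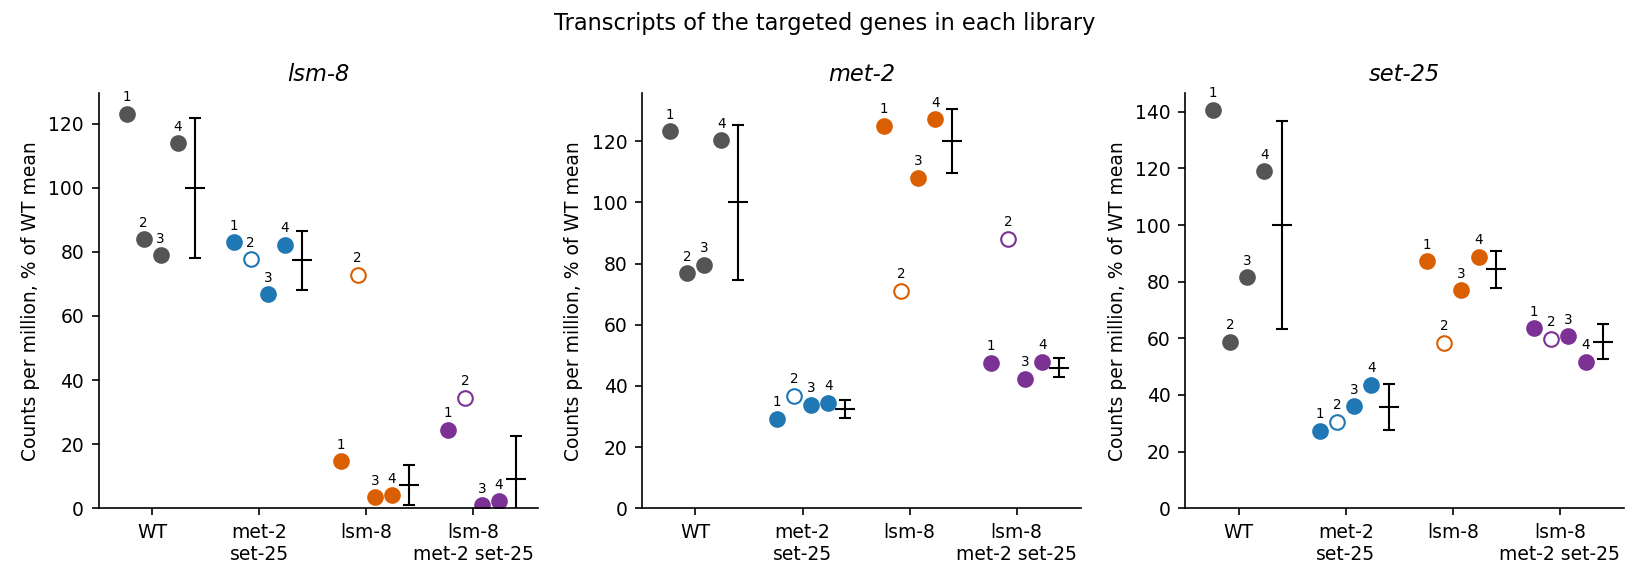
CPM of lsm-8, met-2 and set-25 as a percent of the WT mean, 1 point per library numbered by set, with open circles for the 3 poorly sorted libraries and a bar for the mean ± SD of the others. The lsm-8 transcript reached 72.9% of the WT mean in lsm-8 2 and 34.4% in triple 2, against 0.904% to 24.5% in the other libraries of these strains.

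Splice junction reads inside the deleted genes gave a sharper view. The met-2 intron at III:8376949 to 8377451 had 74 to 123 reads in the WT libraries and 0 to 2 in the met-2 set-25 and triple libraries of sets 1, 3 and 4. It had 70 reads in triple 2 and 10 in met-2 set-25 2. The set-25 intron at III:13288561 to 13288915 had 0 reads in the met-2 set-25 and triple libraries of sets 1, 3 and 4. An intron of lsm-8 at IV:6326601 to 6326827 had 651 to 1019 reads in WT, 100 in lsm-8 1, 172 in triple 1, and 13 to 33 in the lsm-8 and triple libraries of sets 3 and 4. Among all junctions, 21 separated the genotypes in the 13 libraries, with at least 15 scaled reads in each library of some genotypes and at least 10 times less than their lowest value in the others. This choice was made after the data were seen. Among them, 7 junctions were present in the triple mutant alone, in genes such as pals-4, pals-5, eol-1 and C53A5.11, and 3 were absent from met-2 set-25 and the triple mutant, in met-2, set-25 and F20H11.1.

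**Figure D2:**
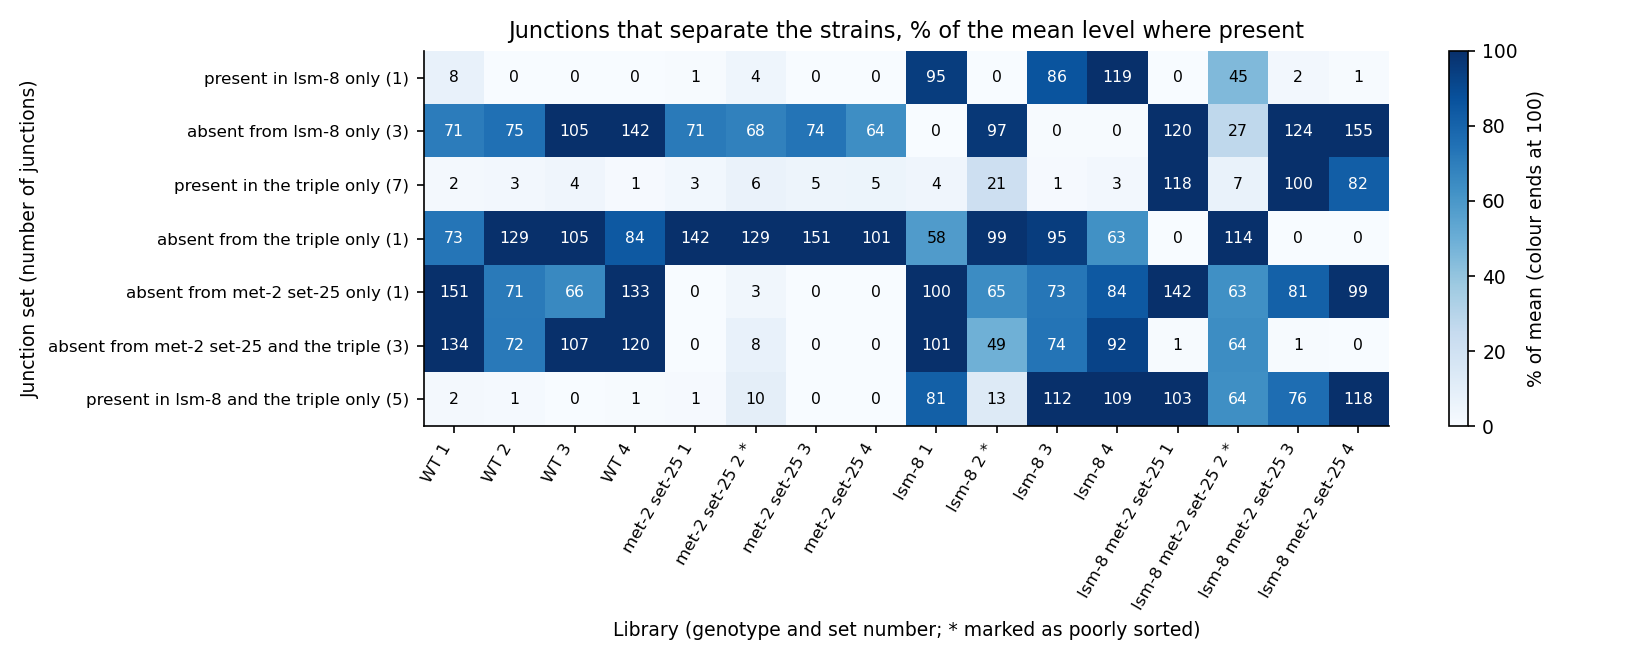
Reads on 7 sets of genotype-separating junctions in the 16 libraries, as a percent of the mean level in the genotypes where the set is present, with an asterisk for the 3 poorly sorted libraries. The junctions absent from met-2 set-25 and the triple mutant reached 64.1% in triple 2, and the junctions present in the triple mutant alone reached 21.3% in lsm-8 2.

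The libraries differed in markers of developmental age within genotypes. Expression of vit-2, which encodes a yolk protein made in the intestine of older worms, ran from 3.40 CPM in met-2 set-25 1 to 3362 CPM in WT 1. WT 2 had 25.2 CPM and lsm-8 3 had 117 CPM. The mean log2 CPM of the sperm list ran from -1.60 in WT 2 to 3.92 in lsm-8 4, and met-2 set-25 1 stood at -0.94 and triple 4 at 3.56. The first principal component of all 16 libraries held 50.2% of the variance. The groups were not balanced for this: the median log2 fold change of the 60 sperm genes was 1.24 in lsm-8, -0.26 in met-2 set-25 and 1.34 in the triple mutant. In edgeR 0 of them passed the threshold or reached an unadjusted p under 0.05 in any of these comparisons, and 0 were called by DESeq2. Camera put the list higher in lsm-8 (adjusted p = 0.00772, and adjusted p = 0.872 with an estimated correlation) and in the triple mutant (adjusted p = 5.7e-06, and adjusted p = 0.975 with an estimated correlation). The fit on 13 libraries is therefore given below also with the mean of this list as a covariate.

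**Figure D3:**
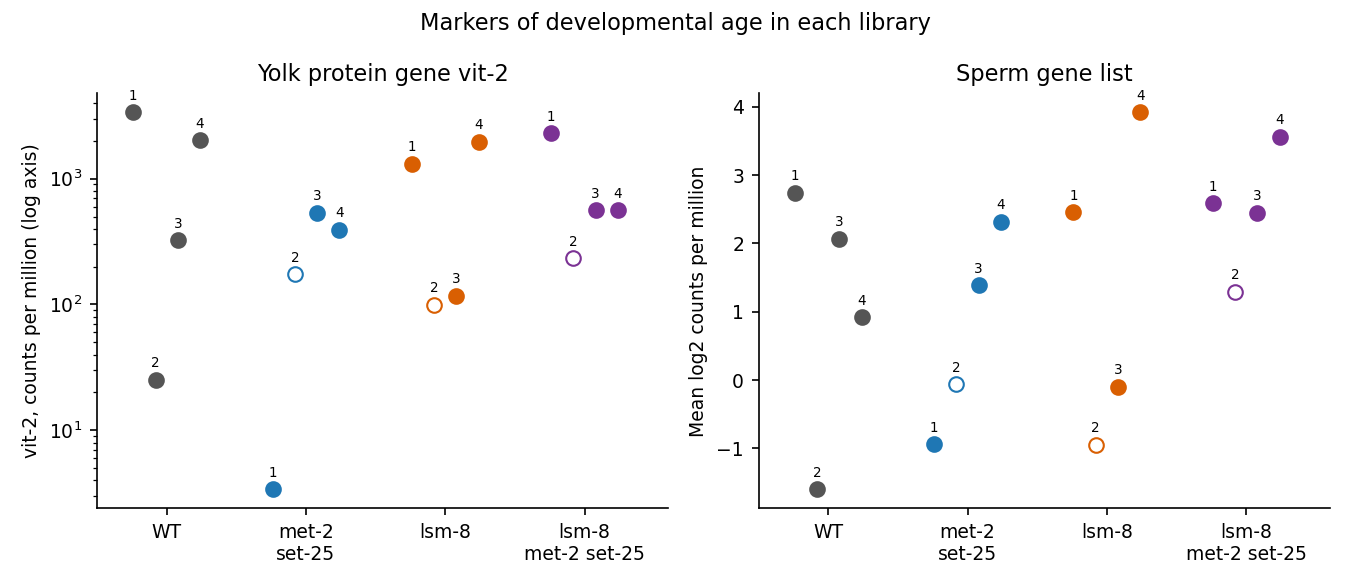
CPM of the yolk protein gene vit-2 (log axis) and the mean log2 CPM of the sperm gene list, 1 point per library numbered by set, with open circles for the poorly sorted libraries. The vit-2 values ran from 3.40 to 3362 CPM, and the libraries of each genotype spread widely.

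The comparison of lsm-8 with WT asks which transcripts depend on the nuclear LSM complex. Among the transcripts that rose in the 13 libraries (n = 4 WT and 3 lsm-8) were clc-32 (WBGene00008631), a claudin-like gene, by a log2 fold change of 6.40 ± 1.02 (SE), and C30H6.12 (WBGene00044238), from 0.627 to 16.45 CPM. The detoxification genes gst-24 (WBGene00001772), a glutathione S-transferase, and ugt-15, a glucuronosyltransferase, rose by 3.2 ± 0.31 and 4.23 ± 0.40, with an adjusted p of 0.00154 each. Transcripts of the splicing factors ddx-23, mog-5 and eftu-2 rose by 0.89 ± 0.13, 0.73 ± 0.13 and 0.79 ± 0.15, and mtr-4, the RNA helicase of the nuclear exosome, by 0.60 ± 0.11. The largest falls were in T09D3.8 (-4.75 ± 0.75), F49C5.11 (-4.42 ± 0.83) and Y58A7A.3 (-3.51 ± 0.58), and the C-type lectin clec-150 fell by 1.73 ± 0.20. A junction at V:5080547 to 5080605 had 0, 0 and 1 reads in lsm-8 1, 3 and 4, but 130, 163 and 184 in triple 1, 3 and 4. Its position falls within Y58A7A.3 in WBcel235 (V:5077854 to 5080903), although the build of the junctions is not given. If it belongs to that gene, the fall of Y58A7A.3 cannot be ascribed to the lsm-8 deletion alone.

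By group, 4 of 33 spliceosome genes rose in lsm-8 and 0 fell, and 14 rose when adjusted over the list alone. Their median log2 fold change was 0.291 (camera adjusted p = 8.23e-07, and adjusted p = 0.814 with an estimated correlation). Of 320 F-box and MATH genes, which encode substrate adaptors of ubiquitin ligases, 12 rose and 0 fell (24 and 0 adjusted over the list alone). Among them bath-13 rose by 2.69 ± 0.34, math-20 by 1.15 ± 0.16 and fbxa-30 by 2.44 ± 0.36. The camera test of this list gave an adjusted p of 0.0031, and an adjusted p = 0.814 with an estimated correlation. Detoxification enzymes had 4 of 177 members higher, cyp-33C8 among them (1.38 ± 0.19), and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.00772, and adjusted p = 0.814 with an estimated correlation). Of the pals genes, an intracellular pathogen response family, 3 of 33 rose (6 adjusted over the list alone): pals-17 by 1.31 ± 0.18, pals-6 by 2.80 ± 0.53 and pals-14 by 3.11 ± 0.64. Their camera test gave an adjusted p of 0.000709, and an adjusted p = 0.814 with an estimated correlation. Nuclear hormone receptors had 3 of 218 members higher, with nhr-112 at 1.21 ± 0.18 (5 adjusted over the list alone, camera adjusted p = 0.00013, and adjusted p = 0.814 with an estimated correlation). Chemoreceptors had 6 of 400 members higher (6 adjusted over the list alone, camera adjusted p = 0.106), with srw-85 at 4.19 ± 0.72 and sri-74 at 5.23 ± 0.83.

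Other lists had few calls over all genes in lsm-8. For the 31 histone genes the median was -0.854, with 0 called in edgeR over all genes, 0 and 3 adjusted over the list alone, 12 lower at an unadjusted p under 0.05 and 3 lower by DESeq2. Camera put them lower (adjusted p = 4.99e-10, and adjusted p = 0.686 with an estimated correlation). Of 76 ribosomal protein genes only rpl-24.2 was called, and it rose by 0.69 ± 0.12, with the same count adjusted over the list alone, while the median of the list was -0.326 (camera adjusted p = 3.93e-16, and adjusted p = 0.814 with an estimated correlation). Of the 8 LSM genes 0 passed over all genes in edgeR, with 2 higher and 4 lower adjusted over the list alone, 2 higher and 5 lower at an unadjusted p under 0.05, and 3 lower by DESeq2 (camera adjusted p = 0.0031, and adjusted p = 0.754 with an estimated correlation). C-type lectins had 1 of 166 higher, clec-5 (1.57 ± 0.25), and 2 lower, clec-53 (-2.10 ± 0.44) and clec-150 (1 and 2 adjusted over the list alone, camera adjusted p = 0.152). The sperm list stood higher in the same libraries by a median of 1.24.

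With 13 libraries 191 genes rose and 56 fell in lsm-8, and 531 and 356 with the sperm covariate, which kept all 247. In the planned fit of 8 libraries 0 genes passed in edgeR, with 1429 at an unadjusted p under 0.05, a lowest adjusted p of 0.246, and 296 called by DESeq2. Leaving out 1 library moved the count of 247 to 463 (WT 1), 161 (lsm-8 3), 84 (WT 4), 82 (lsm-8 1), 77 (WT 3) or 70 (lsm-8 4).

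The comparison of met-2 set-25 with WT asks which transcripts depend on the 2 H3K9 methyltransferases. In the 13 libraries (n = 4 WT and 3 met-2 set-25) clec-126 (WBGene00021117) and clec-6, both C-type lectins, rose by 3.65 ± 0.35 and 3.79 ± 0.39 (adjusted p = 0.000804 and 0.00137). The chemoreceptor gene srw-85 rose by 5.83 ± 0.77 and sri-31 by 3.94 ± 0.66. Of the hedgehog-related genes, which act in the cuticle-forming epidermis, grl-3 rose by 6.80 ± 1.11 and grd-7 by 4.89 ± 0.67. The largest falls were in K09F6.6 (-3.64 ± 0.42), R03D7.2 (-3.6 ± 0.35, WBGene00010989) and the aspartyl protease gene asp-17 (-3.08 ± 0.51).

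Chemoreceptors in met-2 set-25 had 5 of 400 genes higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 5.13e-07, and adjusted p = 0.409 with an estimated correlation). Hedgehog-related genes had 4 of 52 higher (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00197, and adjusted p = 0.555 with an estimated correlation). C-type lectins had 3 of 166 higher (22 adjusted over the list alone, camera adjusted p = 3.28e-06, and adjusted p = 0.193 with an estimated correlation). Lysozymes and immune response genes had 3 of 83 higher, spp-18 by 2.24 ± 0.36, lys-10 by 4.06 ± 0.80 and lys-6 by 2.39 ± 0.47 (10 adjusted over the list alone, camera adjusted p = 2.36e-09, and adjusted p = 0.193 with an estimated correlation). Cuticle collagens had 2 of 168 higher, col-123 by 7.95 ± 1.56 and col-45 by 7.05 ± 1.37 (28 adjusted over the list alone). Camera put the collagens higher (adjusted p = 0.00117, and adjusted p = 0.42 with an estimated correlation), while their median in the 8 libraries was -0.018 with TMM and 0.21 with the authors' scaling. Such cuticle genes pulse with each molt. The mean log2 CPM of the list was 4.28 to 4.48 in the WT libraries and 4.55, 5.70 and 6.13 in met-2 set-25 1, 3 and 4. F-box and MATH genes had 1 of 320 higher, fbxa-136 (2.68 ± 0.40), and 3 lower, fbxa-106 (-2.48 ± 0.33), fbxa-89 and bath-35 (2 and 3 adjusted over the list alone, camera adjusted p = 0.662). Of the 11 H3K9 methylation genes met-2 and set-25 fell and 0 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.00231, and adjusted p = 0.521 with an estimated correlation). Of the 33 pals genes 0 passed over all genes in edgeR, but 7 rose when adjusted over the list alone, with 15 higher at an unadjusted p under 0.05 and 5 by DESeq2. Their median was 0.888 (camera adjusted p = 1.19e-08, and adjusted p = 0.409 with an estimated correlation).

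With 13 libraries 97 genes rose and 12 fell in met-2 set-25, and 248 and 62 with the sperm covariate, which kept all 109. The planned fit had 0 calls in edgeR, with 1121 at an unadjusted p under 0.05, a lowest adjusted p of 0.0674, and 357 called by DESeq2. Leaving out met-2 set-25 3 or WT 4 lowered the count of 109 to 41, and leaving out WT 3 lowered it to 54.

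The triple mutant against WT asks what is lost when both repressive systems are missing. In the 13 libraries (n = 4 WT and 3 triple) pals-5 (WBGene00007659) of the pals family went from 0.528 to 43.5 CPM, a log2 fold change of 6.18 ± 0.69 (SE), and pals-3 rose by 5.16 ± 0.43. The gene F15D4.5 (WBGene00008862) went from 3.6 to 321 CPM (6.34 ± 0.42, adjusted p = 5.1e-05), and clc-32 rose by 7.85 ± 1.06. Both pud-3 (WBGene00017501) and pud-4 (WBGene00017498), paired neighbours on chromosome V, fell: pud-4 went from 141 CPM ± 59.8 to 4.86 ± 1.42, by -5.03 ± 0.45 (adjusted p = 0.000138), and pud-3 by -4.88 ± 0.53. How reads shared by several genes were counted is not stated. Although pud-3 and pud-4 are listed and counted singly here and below, they cannot be read as independent results. The protease gene asp-17 fell by 3.68 ± 0.53 and lipl-5, a lysosomal lipase gene, by 1.28 ± 0.15. The met-2 transcript fell by 1.26 ± 0.15.

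Of 33 pals genes 24 rose and 0 fell in the triple mutant (25 adjusted over the list alone), with a median of 3.6. In the 8 libraries 8 rose (24 adjusted over the list alone), with a median of 3.61 under TMM and RLE and 3.62 with the authors' scaling. The camera test gave an adjusted p of 5.04e-23 in the 13 libraries, and an adjusted p = 0.205 with an estimated correlation. The tables hold no reads of pathogens, so the infection state of the cultures is unknown.

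**Figure D4:**
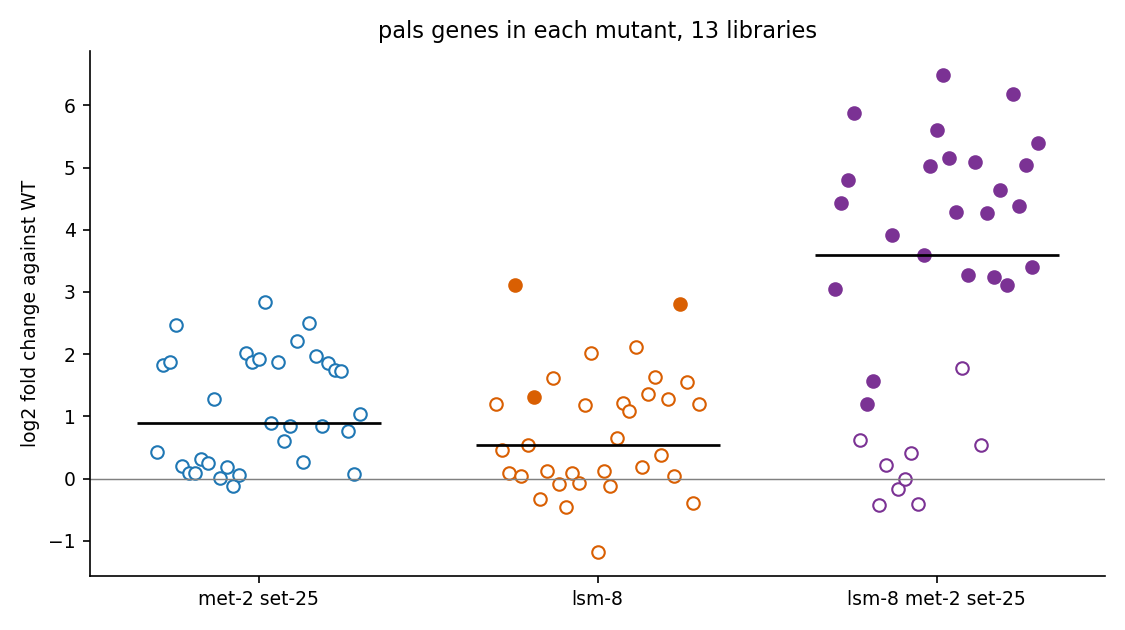
Log2 fold changes against WT of the 33 pals genes in met-2 set-25, lsm-8 and the triple mutant in the fit of 13 libraries, 1 point per gene, filled where the adjusted p was under 0.05, with a line at the median. The medians were 0.888, 0.538 and 3.6, and 0, 3 and 24 genes passed the threshold.

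Of 320 F-box and MATH genes 44 rose in the triple mutant and 1 fell (62 and 2 adjusted over the list alone), and in the 8 libraries 4 rose (10 adjusted over the list alone). The bath-45 transcript rose by 2.81 ± 0.24, fbxa-182 by 3.66 ± 0.39 and fbxa-30 by 3.86 ± 0.37. The camera test gave an adjusted p of 8.73e-07, and an adjusted p = 0.724 with an estimated correlation. Ribosomal protein genes went the other way, with 24 of 76 lower and 0 higher (70 lower and 1 higher adjusted over the list alone) and a median of -0.582. Among them rpl-43 fell by 1.0 ± 0.20, rpl-27 by 0.73 ± 0.16 and rpl-7A by 0.75 ± 0.17. Their camera test gave an adjusted p of 3.01e-26, and an adjusted p = 0.724 with an estimated correlation, and 10 were lower with the sperm covariate. Chemoreceptors had 18 of 400 higher and 2 lower (17 and 2 adjusted over the list alone, camera adjusted p = 0.0923), with sri-74 at 6.56 ± 0.85 and sri-31 at 4.38 ± 0.67. C-type lectins had 10 of 166 higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.0362, and adjusted p = 0.724 with an estimated correlation), with clec-140 at 2.92 ± 0.45. Lysozymes and immune response genes had 6 of 83 higher and 3 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.695), and the antimicrobial peptide genes cnc-2, cnc-4 and cnc-10 rose by 3.80 ± 0.61, 2.13 ± 0.33 and 1.19 ± 0.15. Spliceosome genes had 6 of 33 higher (9 adjusted over the list alone, camera adjusted p = 0.00503, and adjusted p = 0.975 with an estimated correlation), with uaf-2 at 0.86 ± 0.19.

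Detoxification enzymes had 7 of 177 members higher in the triple mutant, with gst-24 at 2.80 ± 0.31, and 6 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.376). Nuclear hormone receptors had 7 of 218 higher and 6 lower (8 and 7 adjusted over the list alone, camera adjusted p = 0.891), such as nhr-53 (1.0 ± 0.20) and nhr-156 (-1.37 ± 0.26). Hedgehog-related genes had 4 of 52 higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.695), with grl-3 at 4.39 ± 1.01. Of the LSM genes, lsm-8 and lsm-3 (-0.55 ± 0.12) fell (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00355, and adjusted p = 0.72 with an estimated correlation). Histones had 2 of 31 lower (2 adjusted over the list alone), his-60 (-1.02 ± 0.26) and his-24 (-2.09 ± 0.56). The camera test gave them an adjusted p of 0.000806, and an adjusted p = 0.724 with an estimated correlation. The median of the sperm list was 1.34 in the same libraries. Intestinal genes had elt-2, a gut transcription factor, higher (1.06 ± 0.18) and vha-6, a proton pump subunit, lower (-1.02 ± 0.22) among 13 (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.787).

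In the planned fit of 8 libraries 63 genes rose and 7 fell in the triple mutant, and 594 were called by DESeq2. With all 13 libraries 674 rose and 421 fell, 67 of the 70 genes among them, and with the sperm covariate 798 and 476. The 3 that did not pass were the collagens col-2 (4.80 ± 1.76, adjusted p = 0.143) and col-37 (5.07 ± 1.97, adjusted p = 0.167), and ZK892.3 (-2.27 ± 1.0, adjusted p = 0.231). Of these, col-37 had 0 reads in WT 1 and WT 3, so no fold is given for the 8 libraries, and 5.23 CPM in WT 2. Leaving out any of WT 1, triple 1, WT 3 and triple 3 from the 8 libraries lowered the count of 70 to 13, 15, 6 and 5, and in the 13 libraries the count of 1095 fell to 597 without WT 4, 581 without WT 3, 512 without triple 1, 437 without triple 3 and 407 without triple 4. The authors' scaling moved the median log2 fold change of all genes to 0.150, from -0.031 with TMM, and in lsm-8 to 0.114, from -0.027. Relative to this, pals, F-box and MATH, spliceosome and ribosomal protein genes kept their direction, the last with a median of -0.428 in the 8 libraries against -0.588 with TMM, while hedgehog-related genes turned from -0.139 to 0.165 and detoxification enzymes from -0.104 to 0.11.

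Set against met-2 set-25, the triple mutant was used to ask what loss of lsm-8 adds when H3K9 methyltransferases are missing. Yet the strains may differ in more than that deletion. A junction of M176.5 had 114 to 184 reads in met-2 set-25 1, 3 and 4 and 0 in triple 1, 3 and 4. Infection of the triple cultures is also unknown, and age markers differed between libraries. The changes below therefore cannot be ascribed to the lsm-8 deletion alone. Within the 8 libraries C38D9.2 (WBGene00008010) rose by 3.2 ± 0.29 (SE), and pud-4, pud-3, asm-3, asm-2 and lipl-5 fell by 6.55 ± 0.36, 6.45 ± 0.46, 4.26 ± 0.38, 2.25 ± 0.23 and 2.02 ± 0.21. Here asm-3 and asm-2 encode acid sphingomyelinases. With 13 libraries (n = 3 and 3) 336 genes rose and 233 fell, all 6 among them. The pals genes had 16 of 33 higher (20 adjusted over the list alone), with a median of 2.43 (camera adjusted p = 2.33e-13, and adjusted p = 0.572 with an estimated correlation). Spliceosome genes had 10 of 33 higher (23 adjusted over the list alone), with a median of 0.537 (camera adjusted p = 3.95e-11, and adjusted p = 0.572 with an estimated correlation). The exosome helicase gene mtr-4 rose by 0.79 ± 0.12. F-box and MATH genes had 27 higher and 2 lower (44 and 3 adjusted over the list alone, camera adjusted p = 5.77e-06, and adjusted p = 0.572 with an estimated correlation). Lysozymes and immune response genes had 3 higher and 12 lower (5 and 16 adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.572 with an estimated correlation), and lys-10 fell by 4.57 ± 0.92 and spp-1 by 1.73 ± 0.31. Intestinal genes had elt-2 higher (0.96 ± 0.20) and 3 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.0282, and adjusted p = 0.572 with an estimated correlation), among them mtl-2, a metallothionein gene, by -2.42 ± 0.35 and ges-1, a gut esterase gene, by -1.10 ± 0.20. In the fit of 8 libraries 1785 genes had an unadjusted p under 0.05 and DESeq2 called 529. Leaving out 1 library lowered the count of 569 to 217, 142 and 199 (met-2 set-25 1, 3 and 4) and to 164, 138 and 114 (triple 1, 3 and 4).

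Against lsm-8, the triple mutant was used to ask what loss of the methyltransferases adds. The same limits hold here, since the M176.5 junction had 65 to 99 reads in lsm-8 1, 3 and 4 and 0 in triple 1, 3 and 4. The changes cannot be ascribed to loss of the methyltransferases alone. Within the 8 libraries C53A5.9, C38D9.2, eol-1 (WBGene00045401), an enzyme gene related to RNA decapping factors, and F15D4.5 rose by 5.33 ± 0.54, 4.60 ± 0.31, 4.57 ± 0.41 and 4.14 ± 0.40, and pud-4 fell by 3.36 ± 0.31. With 13 libraries (n = 3 and 3) 65 genes rose and 16 fell, all 5 among them. The pals genes had 6 of 33 higher (23 adjusted over the list alone), with a median of 2.31 (camera adjusted p = 5.29e-31, and adjusted p = 0.0834 with an estimated correlation). Among them pals-28 rose by 6.78 ± 0.97 and pals-5 by 6.14 ± 0.78. The fit of 8 libraries had 751 genes at an unadjusted p under 0.05, and DESeq2 called 164. Leaving out 1 library lowered the count of 81 to 24, 20 and 44 (lsm-8 1, 3 and 4) and to 23, 13 and 21 (triple 1, 3 and 4).

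The interaction tests whether the effect of losing lsm-8 differs between the 2 backgrounds. Both frm-5.1 and pud-4 passed in the 13 libraries, with an adjusted p of 0.0328 each. The interaction term of pud-4 was -4.53 ± 0.55 (SE), and its mean level was 141 CPM in WT, 50.4 in lsm-8, 311 in met-2 set-25 and 4.86 in the triple mutant. A gene of the FERM domain family by its symbol, frm-5.1, stood at 0.386 CPM ± 0.0765 (SD, n = 4) in WT and had 0 reads in the triple libraries of sets 1, 3 and 4, so no fold is given. EdgeR called 0 genes in the 8 libraries, with 609 at an unadjusted p under 0.05 and 100 by DESeq2. Of the pals genes 0 passed the interaction test in edgeR over all genes, 5 passed adjusted over the list alone, 11 had an unadjusted p under 0.05 and 4 passed in DESeq2 (13 libraries, camera adjusted p = 2.06e-08, and adjusted p = 0.485 with an estimated correlation). Leaving out any of 10 of the 13 libraries moved the count of 2 to 0 or 1, and leaving out WT 2 moved it to 4.

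Many genes called in lsm-8 were also called in the triple mutant. In the 13 libraries 151 of the 191 genes that rose in lsm-8 were among the 674 that rose in the triple mutant, against 7.52 under independence, and 39 of 56 were shared among those that fell, against 1.38. C30H6.12, ugt-15, gst-24, cyp-33C8, clc-32 and sri-74 were among the genes shared upward. Both comparisons use the same WT libraries. With the 4 WT libraries split between the comparisons, 7 to 48 genes were shared upward and 0 to 5 downward over the 6 splits, and the correlation of fold changes across genes, which are not independent replicates, was 0.157 to 0.522, against 0.722 with shared WT libraries. Simulated groups without change that share WT gave a mean correlation of 0.42. Between the 8-library fits 0 genes were shared, since edgeR called 0 in lsm-8.

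Genes that rose in the triple mutant lay more often on the chromosome arms, the regions where H3K9 methylation is enriched. Of 60 autosomal genes that rose in the 8 libraries, 50 (83.3%) lay on the arms, against 59.4% of the 14428 autosomal genes tested (Fisher's exact test, two-sided, odds ratio 3.44, adjusted p = 0.00099). Of 588 in the 13 libraries 418 did (71.1%, odds ratio 1.73, Fisher's exact adjusted p = 1.3e-08), and of the 383 that fell 59.3% did. In met-2 set-25 65 of 88 genes that rose lay there (73.9%, odds ratio 1.95, Fisher's exact adjusted p = 0.0116). In lsm-8 114 of 175 did (65.1%, odds ratio 1.29, Fisher's exact adjusted p = 0.203). With the narrower alternative arms 91 of 175 did (52%, against 41.14% of those tested, odds ratio 1.559, Fisher's exact adjusted p = 0.00824). With the sperm covariate and the wider arms 271 of 475 did (57.05%, odds ratio 0.9106, Fisher's exact adjusted p = 0.39). The result for lsm-8 therefore depended on the setting. The difference between lsm-8 and the other mutants was not tested. Fisher's test treats genes as independent, which related genes that lie close together, such as pals-3 and pals-5 on chromosome I, need not be. Its p-values may therefore be too small.

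Among repeats, 2 families of LTR retrotransposons stood out, mainly through reads on a few copies. Reads on CER10-I_CE rose in met-2 set-25 by 1.74 ± 0.29 (SE, adjusted p = 0.0315) and in the triple mutant by 2.78 ± 0.30 (adjusted p = 0.000624) in the 8 libraries, and in the 13 libraries from 2.58 CPM (reads scaled to the gene counts) in WT to 9.66 and 21.5, with 5.0 in lsm-8. CER3-I_CE rose in the triple mutant by 3.11 ± 0.44 (adjusted p = 0.00345), and stood at 2.94 CPM in WT, 2.2 in met-2 set-25, 5.2 in lsm-8 and 26.5 in the triple mutant. Most CER10-I_CE reads of the triple mutant lay on adjoining copies at V:8475654 to 8480094 and V:8480088 to 8481470 (11.9 and 9.48 CPM). The CER3-I_CE copy at V:18119870 to 18121325 held 22.2 CPM there. These rises therefore do not describe all copies of a family, and such a copy and its family are not separate results. The DNA transposon family CEMUDR1 rose in the triple mutant by 0.96 ± 0.19 (adjusted p = 0.0419). Whether CER3-I_CE differed between the mutants was not tested. EdgeR called 0 of 263 families in lsm-8 in the 8 libraries, with 17 at an unadjusted p under 0.05 and 0 by DESeq2, and in the 13 libraries 5 rose, among them CER12-I_CE (1.24 ± 0.25) and CER10-I_CE (0.88 ± 0.19). The totals of all repeats did not separate: they were 4298 CPM ± 493 (SD, n = 4) in WT, 4439 ± 594 in met-2 set-25, 5037 ± 601 in lsm-8 and 4714 ± 367 (n = 3 each) in the triple mutant.

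**Figure D5:**
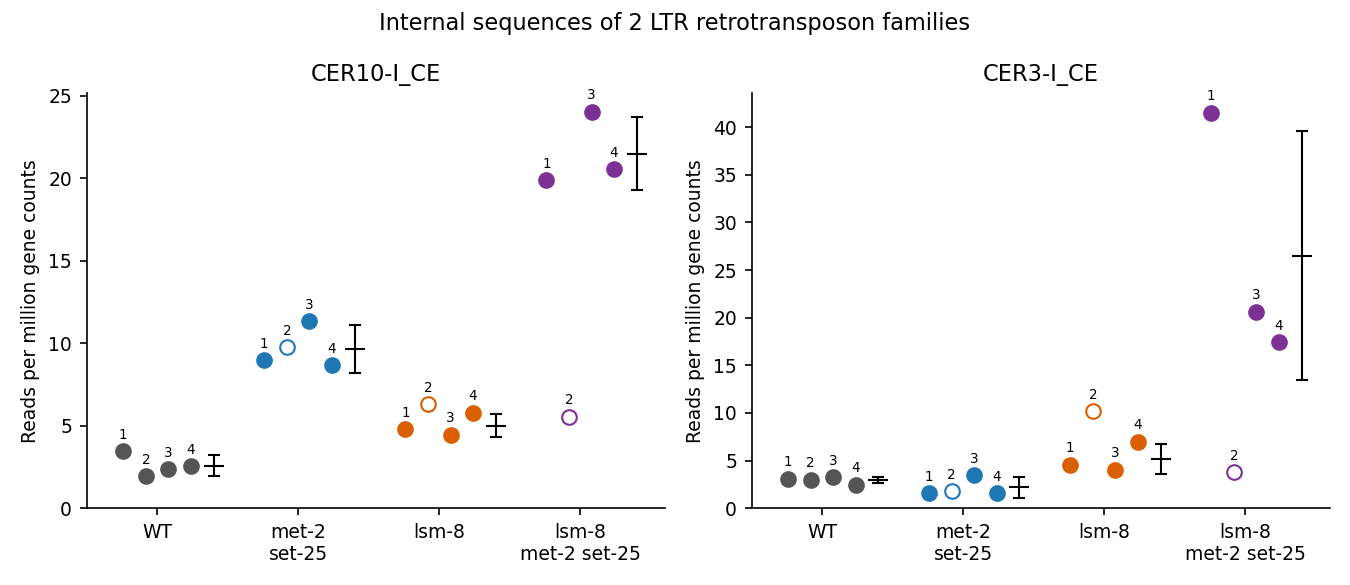
Reads relative to gene counts (CPM) on the internal sequences CER10-I_CE and CER3-I_CE, 1 point per library numbered by set, with open circles for the poorly sorted libraries and a bar for the mean ± SD of the others. The means of CER10-I_CE were 2.58 in WT, 9.66 in met-2 set-25, 5.0 in lsm-8 and 21.5 in the triple mutant, and those of CER3-I_CE were 2.94, 2.2, 5.2 and 26.5.

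Single repeat copies gave 7 higher and 0 lower in lsm-8, 1 and 2 in met-2 set-25, and 51 and 4 in the triple mutant, of 8127 tested in the 8 libraries. The counts with 13 libraries were 41 and 3, 23 and 13, and 130 and 25. Copies that rose in the triple mutant included CEMUDR1 at IV:2902769 to 2909930 (2.61 ± 0.42), CER3-I_CE at V:18119870 to 18121325 (3.32 ± 0.47) and Mariner5_CE at II:2076941 to 2077907 (4.69 ± 0.79), and a CELE45 copy at IV:9014433 to 9014694 fell by 2.60 ± 0.48. As lists of copies in the 8 libraries, LINE, SINE and RTE had 0 of 261 called in met-2 set-25, and camera put the list lower (adjusted p = 0.00151, and adjusted p = 0.115 with an estimated correlation). With 13 libraries 1 of 253 rose and 3 fell there (camera adjusted p = 5.27e-05, and adjusted p = 0.167 with an estimated correlation). Simple repeat copies had 6 of 747 higher and 7 lower in the triple mutant with 13 libraries (camera adjusted p = 0.0472, and adjusted p = 0.88 with an estimated correlation). By its name pattern, the LTR list also took in the CeRep names of the satellite list. As lists of families, the LTR list had 0, 1 and 2 of 51 higher in lsm-8, met-2 set-25 and the triple mutant in the 8 libraries, with 0 lower. Camera put the list lower in met-2 set-25 (adjusted p = 0.00274, and adjusted p = 0.177 with an estimated correlation). The hAT, MuDR, Helitron, Mirage and Merlin list had 1 of 31 higher in the triple mutant, CEMUDR1. By edgeR, 0 families of the LINE, SINE and RTE (12), Tc and mariner (13), simple repeat (95) and satellite (12) lists were called in any of these comparisons in the 8 libraries, and their lowest camera adjusted p was 0.15. With 13 libraries 3, 1 and 5 of 49 families of the LTR list and 1, 1 and 3 of the hAT, MuDR, Helitron, Mirage and Merlin list rose, and 0 fell. Of 92 simple repeats 1 rose in lsm-8, 1 fell in met-2 set-25 and 2 rose in the triple mutant, and 1 Tc or mariner family rose in the triple mutant. Camera put the LTR list lower in met-2 set-25 again (adjusted p = 0.000682, and adjusted p = 0.372 with an estimated correlation). It put simple repeats lower in lsm-8 (adjusted p = 0.0274, and adjusted p = 0.704 with an estimated correlation) and in the triple mutant (adjusted p = 0.00287, and adjusted p = 0.625 with an estimated correlation). For the CER names followed by a digit, a list made after the data were seen that leaves out the CeRep names, 0, 1 and 2 of 36 rose in the 8 libraries. Camera put that list higher in lsm-8 (adjusted p = 0.0471, and adjusted p = 0.333 with an estimated correlation) and lower in met-2 set-25 (adjusted p = 0.0127, and adjusted p = 0.27 with an estimated correlation). With 13 libraries 3, 1 and 5 of 34 rose. The list then stood higher in lsm-8 (adjusted p = 0.0305, and adjusted p = 0.547 with an estimated correlation), lower in met-2 set-25 (adjusted p = 0.000398, and adjusted p = 0.217 with an estimated correlation) and higher in the triple mutant (adjusted p = 0.0255, and adjusted p = 0.573 with an estimated correlation). With the sperm covariate it stayed lower in met-2 set-25 (adjusted p = 8.09e-05, and adjusted p = 0.0354 with an estimated correlation), and the camera adjusted p was 0.415 in lsm-8 and 0.894 in the triple mutant. Copies of these names (92 with 13 libraries) were higher in lsm-8 (camera adjusted p = 0.00146, and adjusted p = 0.327 with an estimated correlation), lower in met-2 set-25 (camera adjusted p = 0.0157, and adjusted p = 0.39 with an estimated correlation) and higher in the triple mutant (camera adjusted p = 0.00056, and adjusted p = 0.257 with an estimated correlation). In the 8 libraries the copies were called in lsm-8 (camera adjusted p = 0.0301, and adjusted p = 0.783 with an estimated correlation) but not in met-2 set-25 (0.18) or the triple mutant (0.114). With the sperm covariate they were called lower in met-2 set-25 (camera adjusted p = 0.0134, and adjusted p = 0.157 with an estimated correlation), but not in lsm-8 (0.0669) or the triple mutant (0.198).

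The nuclear LSM complex is part of the U6 snRNP, so the use of splice junctions was compared. In the 8 libraries 41 junctions of 4215 tested gained share within their cluster in lsm-8 and 10 lost it, in 48 clusters of 46 genes, while in the triple mutant 3 gained and 0 lost. With 13 libraries 101 gained and 17 lost (4802 tested), and in the triple mutant 62 gained and 6 lost. In met-2 set-25 edgeR called 0 in both, with 60 and 81 at an unadjusted p under 0.05. Of the 118 and 68 junctions called in the 13 libraries, 63 were shared between lsm-8 and the triple mutant, all in the same direction. Both comparisons use the same WT libraries. With these split between the comparisons, a test added after the data were seen, 5 to 13 junctions were shared over the 6 splits, all in the same direction, against 0.0725 to 0.254 under independence.

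A junction of 395 nt in the cluster of rps-23, a ribosomal protein gene, at IV:12390458 to 12390852, had 0 reads in all WT and met-2 set-25 libraries outside the poorly sorted ones. It took 0.116% ± 0.0454 (SD, n = 3) of its cluster in lsm-8 and 0.117% ± 0.0173 (n = 3) in the triple mutant, with 29 to 56 reads per library. In eef-1G, a translation elongation factor gene, V:10966363 to 10966505 took 2.42% ± 1.08 in lsm-8 and 1.51% ± 0.294 in the triple mutant, against 0.0716% in WT. In npa-1, V:7078739 to 7078888 took 1.43% ± 0.19 and 1.11% ± 0.443, against 0.0833% in WT. In pals-24, III:120516 to 120635 took 77.7% and 64.6%, against 4.96% in WT. Of the junctions that were the most used of their cluster, 3 lost share in lsm-8 and 0 in the triple mutant. In Y39A3CL.7, III:1830597 to 1831803 took 96.4% ± 3.59 in lsm-8, 1.46% in WT and 0.746% in the triple mutant, and its neighbour III:1830908 to 1831803 took 0% in lsm-8, 48.1% in WT and 47.7% in the triple mutant. In sma-10, IV:275616 to 275842 took 37.4% ± 14.5 in lsm-8 and 2.66% in the triple mutant, and had 0 reads in WT. The triple mutant also carries the lsm-8 deletion, so these levels in Y39A3CL.7 and sma-10 cannot be ascribed to that deletion alone. Their cause was not tested.

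Rare junctions, those under 5% of their cluster, took 0.698% ± 0.050 (SD, n = 4) of the reads in WT, 0.732% ± 0.046 in met-2 set-25, 0.981% ± 0.17 in lsm-8 and 0.867% ± 0.023 (n = 3 each) in the triple mutant. The mean of the 6 libraries with the lsm-8 deletion was 0.924% and that of the other 7 was 0.713% (difference 0.211, exact permutation test, two-sided, p = 0.000583, the smallest that 1716 regroupings can give). This test did not adjust for age. Within WT the share followed the sperm list mean, from 0.63% in WT 2 (-1.60) to 0.737% in WT 1 (2.74). The library lsm-8 4 was highest in both (1.173% and 3.92), while lsm-8 3 had 0.88% at a sperm mean of -0.10. How much of the difference comes from age was not tested. Of 1070 tested junctions with another donor than the most used one of their cluster 4.67% gained share in lsm-8, and of 1283 with another acceptor 3.74% did (Fisher's exact test, two-sided, p = 0.3). Leaving out lsm-8 4, WT 3, lsm-8 1 or WT 1 lowered the count of 51 in the 8 libraries to 2, 15, 17 or 26.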

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

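The tests of the junction levels in this part were chosen after the levels had been seen, while the tests on WT libraries and on the interaction were planned.

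Junctions that separate the genotypes gave unexpected levels in the poorly sorted libraries of set 2, which no comparison of the study used. The level is given as a percent of the mean in the genotypes where the junctions are present. Outside these libraries, the junction present in lsm-8 alone also had 13 reads (7.73%) in WT 1, a library of both fits. It had 5 reads (2.4%) in triple 3 and 0 in WT 2, 3 and 4. In the library labelled triple 2 the junction present in lsm-8 alone stood at 44.7%, the 3 junctions absent from met-2 set-25 and the triple mutant at 64.1%, the 7 present in the triple mutant alone at 6.93%, and the junction of M176.5, absent from the triple mutant alone, at 114%. In the library labelled lsm-8 2 the 7 junctions present in the triple mutant alone stood at 21.3%, the 3 absent from met-2 set-25 and the triple mutant at 49%, the 5 present in lsm-8 and the triple mutant at 13%, and the junction of M176.5 at 98.7%. The library labelled met-2 set-25 2, of a strain without a balancer, had 4.45% of the junction present in lsm-8 alone and 6.42% of those present in the triple mutant alone. It had 7.71% of the 3 absent from met-2 set-25 and the triple mutant. The 5 present in lsm-8 and the triple mutant stood at 9.55% there, against 0.29% to 0.986% in met-2 set-25 1, 3 and 4. The 3 junctions absent from lsm-8 alone stood at 27% in triple 2 and 96.7% in lsm-8 2, and the 1 of them that lies apart from the others, at V:5080547, had 27 and 93 reads. Some of the 7 junctions present in the triple mutant alone lie in genes that rose there, such as pals-5 and eol-1. Their level can therefore follow expression as well as the share of triple mutant worms, and is not a strain marker by itself.

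If the poorly sorted libraries held only balanced siblings of their own strain, the 3 junctions absent from met-2 set-25 and the triple mutant, would be missing from triple 2, and their 64.1% (70 reads in met-2, 21 in set-25 and 127 in F20H11.1) argues against that. Worms of other strains mixed in under correct labels would leave lsm-8 2 with the junction present in lsm-8 alone, which had 0 reads there, a level of 0%. Strain mixtures together with an exchange of the labels of lsm-8 2 and triple 2 would place that junction in triple 2, where it reached 44.7%. This stays a hypothesis, since the M176.5 junction, at 98.7% in lsm-8 2 and 58.2% to 151% in the libraries of the 13 that hold it, leaves room for only a part of triple mutant worms there. No biological explanation was tested, and no result of the 13 libraries uses these samples.

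In the WT group of 4 libraries, 3 of 33 measures had 1 library farther from the rest than chance gives in about 1 of 20 groups, and each time it was WT 2. Its mean log2 CPM was 3.33 for lysozymes and immune response genes (the median of the 4 WT libraries was 2.98), 3.18 for detoxification enzymes (median 2.68) and 1.96 for neuropeptides and insulins (median 1.71). At that limit some of 33 measures would pass by chance, and measures on the same 4 libraries are not independent. In the interaction test of edgeR on 13 libraries frm-5.1 and pud-4 passed, each with an adjusted p of 0.0328. In the 8 libraries 0 genes passed that test (lowest edgeR adjusted p of 0.0674). Leaving out each library in turn gave 0 to 4 calls in the 13 libraries.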

How the results depend on the processing

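Alternatives added after seeing the data were DESeq2 and leave-one-out on 13 libraries, the first principal component, fits without pairs of libraries, the sperm covariate for repeats and junctions, and a split of WT for shared junctions. Not planned either were chromosome arms, shared genes and levels of the deleted genes on 13 libraries. The 226 named gene results kept their direction in all 3618 comparisons with another setting. The counts below depend on the number of libraries and on the covariate fitted. Simulated log2 changes of 2 were recovered for 12%, 16% and 24% of genes in the 8 libraries and 54%, 58% and 50% in the 13, in lsm-8, met-2 set-25 and the triple mutant. For junctions the shares were 2% and 6.1% in the 8 and 18.8% and 14% in the 13, in lsm-8 and the triple mutant. For repeat copies they were 10% and 0% in the 8. False calls were 0 of 12, 5 of 21 and 3 of 27 gene calls in the 8 libraries and 1 of 65, 5 of 77 and 0 of 54 in the 13. For families in the 8 they were 3 of 12 in lsm-8 and 0 of 8 in the triple mutant. Where no cause is named, the cause was not tested. Counts follow the order lsm-8, met-2 set-25 and triple against WT, triple against met-2 set-25, triple against lsm-8, interaction. In the 8 libraries they were 0, 0, 70, 6, 5 and 0 genes, for the first 3 comparisons 7, 3 and 55 repeat copies, 0, 1 and 3 families and 51, 0 and 3 junctions, and 15, 21, 10, 17, 9 and 19 gene lists.

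With 13 libraries there were 247, 109, 1095, 569, 81 and 2 genes, 44, 36 and 155 copies, 5, 4 and 12 families, 118 junctions in lsm-8 and 68 in the triple mutant, and 151 genes shared upward and 39 downward by both. More libraries per group explain part of this by construction. The sperm covariate gave 887, 310, 1274, 516, 189 and 7 genes, 47, 50 and 135 copies, 5, 6 and 12 families, and 125 and 61 junctions. The first principal component gave 1349, 349 and 1911 genes, 212 against lsm-8 and 11 in the interaction. Without WT 2 and met-2 set-25 1 there were 677 in the triple mutant, 313 against met-2 set-25 and 10 in the interaction, and without lsm-8 1 and triple 1 there were 33, 44, 281, 61, 7 and 0. All 16 libraries gave 24, 174, 609 and 246 genes in the first 4 comparisons. DESeq2 called 296, 357, 594, 529, 164 and 100 genes in the 8 libraries, 967, 598, 2022, 1572, 360 and 116 in the 13, and 22 copies in lsm-8. Limma on the authors' values gave 1, 34, 172, 62, 14 and 7 genes. With no low-count filter there were 19, 107, 32, 10 and 1 genes from met-2 set-25 on, 15 copies in lsm-8, and 3, 4 and 8 families. The 4 compared libraries alone gave 45 genes in met-2 set-25, 0 in the triple mutant, 85 against met-2 set-25 and 2 against lsm-8, with fewer residual degrees of freedom. TMM from the repeat counts left 1 copy and 0 families in met-2 set-25. A minimum of 30 reads gave 20 and 9 junctions in lsm-8 and the triple mutant, with fewer tested. With an estimated correlation 0 gene lists were called in each of the 6 comparisons. With the WT libraries split between both comparisons, 7 to 48 genes were shared upward and at most 5 downward, and 5 to 13 junctions instead of 63, with fewer WT libraries in each comparison.

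No pairing of replicates was assumed. The study's replicate number as a block gave 37 genes in the triple mutant, 16 against met-2 set-25 and 0 against lsm-8, 27 copies in lsm-8, 2 and 6 families in met-2 set-25 and the triple mutant, and 7 junctions in the triple mutant. The set number as a block of the 13 libraries gave 103, 89, 614, 737, 52 and 4 genes. Correlations of residuals between libraries of the same study number ran from -0.021 to 0.566 in 12 pairs, 4 of them over 0.1, and between different numbers from -0.566 to 0.021, 0 of them over 0.1. All 8 libraries matched their own number best, but with 2 libraries per group the residuals of a group mirror each other. For set numbers, 18 pairs of the same number ran from -0.682 to 0.662 (median 0.026), and 4 of 13 libraries matched their own number best.

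Leaving out each library, where a lone library of a group is assumed to vary like the others, gave these ranges in the 8 libraries. The 0 genes in lsm-8 and in met-2 set-25 stayed 0 to 0. In the triple mutant 70 became 5 to 15 (5 without triple 3, 6 without WT 3, 13 without WT 1, 15 without triple 1). Against met-2 set-25, 6 became 0 to 3 (0 without triple 3, 1 without triple 1 or met-2 set-25 3, 3 without met-2 set-25 4), and against lsm-8, 5 became 0 to 2 (0 without lsm-8 1, lsm-8 4 or triple 3, 2 without triple 1). The interaction gave 0 to 5 (5 without triple 3, 3 without WT 1, 1 without triple 1). Copies gave 8 to 65 in lsm-8 (65 without WT 1, 21 without lsm-8 1, 11 without WT 3), 1 to 20 in met-2 set-25 (20 without WT 3, 15 without WT 1, 13 without met-2 set-25 4, 1 without met-2 set-25 3) and 50 to 87 in the triple mutant (87 without WT 1). Families gave 0 to 0, 0 to 1 (0 without WT 1, WT 3 or met-2 set-25 3) and 1 to 2 (1 without WT 1). Junctions gave 2 to 26 in lsm-8 (2 without lsm-8 4, 15 without WT 3, 17 without lsm-8 1, 26 without WT 1), 0 to 0 in met-2 set-25, and 1 to 6 in the triple mutant (6 without WT 1, 1 without triple 1 or triple 3). In the 13 libraries lsm-8 gave 70 to 463 (463 without WT 1, 161 without lsm-8 3, 84 without WT 4, 82 without lsm-8 1, 77 without WT 3, 70 without lsm-8 4), met-2 set-25 41 to 123 (41 without WT 4 or met-2 set-25 3, 54 without WT 3), and the triple mutant 407 to 1442 (597 without WT 4, 581 without WT 3, 512, 437 and 407 without triple 1, 3 and 4). Against met-2 set-25 the range was 114 to 217 and against lsm-8 13 to 44, with every library left out moving the count (217, 142 and 199 without met-2 set-25 1, 3 and 4, and 164, 138 and 114 without triple 1, 3 and 4; 24, 20 and 44 without lsm-8 1, 3 and 4, and 23, 13 and 21 without triple 1, 3 and 4). The interaction gave 0 to 4 (4 without WT 2, 3 without met-2 set-25 1 or lsm-8 4, 1 without WT 1, and 0 without any of the other 9).

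With arms as the outer 2 of 4 parts, 66.7% of the autosomal genes that rose in the triple mutant in the 8 libraries lay there, against 41.3% of those tested. Of those that rose in lsm-8 in the 13 libraries 52% did, against 41.14% (odds ratio 1.559, Fisher's exact adjusted p = 0.00824). The wider arms had given lsm-8 a Fisher's exact adjusted p of 0.203. The targeted genes, RLE size factors, the filter of 50 counts and the minimum fold change of 1 left the results within 1.5 times of the counts above. Reads near 0 limit what can be said of col-37 and math-5, with 0 reads in the WT libraries of the 8, and of frm-5.1, with 0 reads in the triple libraries of the 13.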

Other observations

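The tests of infection, pals-22, age for the pals genes and junctions, and junction depth in this part were chosen after the results had been seen, as were the other splits of the samples, except those with the sperm covariate and the test on chromosome IV, whose outcomes were written down before. Some groups of genes have not been described yet. Of the neuron list, 0 of 16 genes passed in edgeR in lsm-8, met-2 set-25 or the triple mutant (13 libraries), with 0, 1 and 1 at an unadjusted p under 0.05 and 0 by DESeq2, and 0 adjusted over the list alone. Body wall muscle had 0 of 15 called, with 0, 0 and 3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 adjusted over the list alone, and camera put it lower in the triple mutant (adjusted p = 0.0114, and adjusted p = 0.975 with an estimated correlation). In the pharynx list phat-3, a mucin-like gland gene, rose in the triple mutant (1.23 ± 0.24, 1 of 16 over all genes and adjusted over the list alone), where camera put the list lower (adjusted p = 0.0337, and adjusted p = 0.975 with an estimated correlation). Neuropeptide and insulin genes had 3 of 126 higher in the triple mutant, among them nlp-4 (1.71 ± 0.42) and ins-20 (3.02 ± 0.77), and 1 adjusted over the list alone. In met-2 set-25 edgeR called 0 of them, with 27 higher at an unadjusted p under 0.05 and 1 by DESeq2, and camera put the list higher (adjusted p = 7.8e-10, and adjusted p = 0.417 with an estimated correlation). Of 84 homeobox genes ceh-79 rose in lsm-8 (0.86 ± 0.18, 1 adjusted over the list alone), and in the triple mutant ceh-91 rose (0.96 ± 0.25) and nob-1, a posterior Hox gene, fell by 0.69 ± 0.18 (0 adjusted over the list alone). Heat shock genes had 0 of 15 called in edgeR, with 3, 0 and 2 lower at an unadjusted p under 0.05 and 1, 0 and 2 lower by DESeq2, and camera put them lower in lsm-8 (adjusted p = 0.0031, and adjusted p = 0.814 with an estimated correlation).

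Chromatin and decay factors other than those deleted also had few calls. Of 14 Polycomb genes cec-1, a chromodomain gene, fell in the triple mutant (-0.86 ± 0.19, 1 adjusted over the list alone), and of 11 H3K9 methylation genes lin-13 rose there (0.85 ± 0.16, 1 higher and 2 lower adjusted over the list alone). Of 36 RNA decay factors mtr-4 was called in lsm-8 (1 higher and 1 lower adjusted over the list alone) and the triple mutant (0.43 ± 0.11, 0 adjusted over the list alone). In met-2 set-25 edgeR called 0 of these factors, with 7 lower at an unadjusted p under 0.05 and 0 by DESeq2, and camera put the list lower (adjusted p = 4.86e-09, and adjusted p = 0.409 with an estimated correlation). There the spliceosome list also had 0 of 33 called, with 8 lower at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 2.36e-09, and adjusted p = 0.409 with an estimated correlation). Germline genes had 0 of 36 called in the 3 mutants, with 1, 0 and 2 at an unadjusted p under 0.05 and 1, 0 and 0 by DESeq2, and camera put them lower in met-2 set-25 (adjusted p = 0.000915, and adjusted p = 0.693 with an estimated correlation). Oocyte and yolk genes had 0 of 23 called, with 0, 3 and 0 at an unadjusted p under 0.05 and 0, 2 and 0 by DESeq2, and camera put them lower in met-2 set-25 (adjusted p = 0.00058, and adjusted p = 0.68 with an estimated correlation). Molting genes had 0 of 21 called, with 1, 0 and 5 lower at an unadjusted p under 0.05 and 0, 0 and 2 by DESeq2 (camera adjusted p = 0.0498 in the triple mutant, and adjusted p = 0.975 with an estimated correlation). The germline, sperm, oocyte, molting and collagen lists all change with age in larvae of these stages. Cuticle collagens had 0 of 168 called in lsm-8, with 26 at an unadjusted p under 0.05 and 9 by DESeq2, and col-176 rose in the triple mutant (2.31 ± 0.55, 0 adjusted over the list alone).

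The rise of the pals genes in the triple mutant was set against 3 explanations. Developmental age as the whole cause is argued against, since 24 of 24 genes stayed called with the sperm covariate, with a median of 4.53 against 4.4 without it. A strain variant that lowers the transcript of pals-22, a known repressor of this family, is argued against by its log2 fold change of -0.17 ± 0.21 (adjusted p = 0.703), although a variant that alters only the protein was not tested. Infection of the triple cultures stays open, because the tables hold no pathogen reads and the lowest pals-5 level in the triple libraries, 29.7 CPM, was far above the highest in WT (0.853) and in the other mutants of the 13 libraries (3.73). A genetic effect of the combined mutations may also account for it, as a hypothesis that these libraries cannot set apart from infection.

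The gain of junctions shared by lsm-8 and the triple mutant was set against variants linked to lsm-8, age and depth. Of the 63 shared junctions 22.2% (14) lay on chromosome IV, against 18.5% of those tested (Fisher's exact test, p = 0.417), which argues against linked variants as the whole cause. Age as the whole cause is argued against, since 102 of 118 junctions stayed called in lsm-8 with the sperm covariate, and depth is argued against by a ratio of the mean junction totals of lsm-8 to WT of 1.01. That loss of lsm-8 itself alters splice site use is a hypothesis, found and tested on the same data.

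Other splits of the 7 libraries of a comparison with WT in the fits of 13 libraries (35 splits each, the real one included) gave these results. The smallest share they can give is 1 of 35, and shares were not adjusted for the number of results tested. That chance can be excluded therefore means only a share under 0.05 for each result taken alone. In lsm-8, chance cannot be excluded for the 247 genes, since 2 of 35 splits gave as many, and the highest other had 1017: it set lsm-8 1, lsm-8 4 and WT 1 against the rest and, with several times the real count, points to a structure of the samples. These 3 had the highest sperm list means of the 7 (2.46, 3.92 and 2.74, against -1.60 to 2.07), as age would give, although vit-2 was 2018 CPM in WT 4 and 1317 CPM in lsm-8 1. With the sperm covariate chance can be excluded for lsm-8 (887 genes, 1 of 35, highest other 281) and met-2 set-25 (310, highest other 8). It cannot for the triple mutant, where 2 of 35 splits gave as many as the real 1274 and the highest other had 1348. Without the covariate chance can be excluded for met-2 set-25 (109 genes, highest other 4) and the triple mutant (1095 genes, highest other 416), its 24 pals genes (highest other 0) and its 24 ribosomal protein genes (highest other 0). For repeat copies chance can be excluded in lsm-8 (44, highest other 30), met-2 set-25 (36, highest other 11) and the triple mutant (155, highest other 100). For repeat families the real split gave the highest count in lsm-8 (5, highest other 4) and the triple mutant (12, highest other 11). Both have a share of 1 of 35, which is under 0.05, but they exceed the highest other count only narrowly. Chance is therefore not called excluded for these families, a stricter reading than the share alone. In met-2 set-25 (4, highest other 41) chance cannot be excluded either, and that other split, with several times the real count, points to a structure of the samples. For junctions chance can be excluded in lsm-8 (118, highest other 43) and the triple mutant (68, highest other 13). In met-2 set-25 the splits of junctions say nothing about chance, because with a real count of 0 all 35 must give as many (highest other 20). For the triple mutant against met-2 set-25 (569 genes, highest other 0) and against lsm-8 (81 genes, highest other 0) the 10 splits are too few for a share under 0.05.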
